A study of Mus musculus with 8 samples.

How the data were processed

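RNA was measured in 8 libraries of stromal cells sorted from the mouse small intestine. The cells lacked CD45 and CD31, which mark leukocytes and endothelial cells, and carried YFP. They came from mice with a floxed gene for the lymphotoxin β receptor and a PDGFRα/YFP allele combination named in the labels. Sorting on surface PDGFRα gave the 2 groups, PDGFRα- and PDGFRα+, with 4 libraries each. Replicate numbers 1 to 4 come from the sample titles. The labels do not state whether the libraries came from separate mice, so the p-values measure only the spread between these libraries, which may be partly technical. Both groups carry YFP and come from the same kind of mouse, and no library without the floxed allele was analysed here.

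Per the labels' protocols, sorted cells were collected in lysis buffer and libraries were made with a stranded total RNA kit for very small inputs (SMARTer Stranded Total RNA-Seq Pico) and sequenced on an Illumina NextSeq instrument. Per the submitters' processing notes, the tools were cutadapt 3.4, STAR 2.7.3a, featureCounts 2.0.1 and DESeq2, and the build was GRCm38, also called mm10. The parameters, the strand setting of the counting and the annotation release are not given in the sources used here. The authors deposited 1 table with whole-number raw read counts per gene and library, without normalization. The same table holds the authors' counts divided by a size factor and rounded, read here as a score and not tested, and the deposited group means of that score. It also holds the authors' comparison of the groups as a ratio (fold change), a log2 fold change, a p-value and an adjusted p-value per gene.

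The table had 53801 rows, all with mouse Ensembl gene identifiers and none without a gene. Of these identifiers, 53620 are in GENCODE M21, the GRCm38 annotation used here for symbols and positions, and 24547 rows held 0 counts in all libraries. Total counts per library, in units of 1e+06, ran from 12.9 to 35.1. No libraries held identical values, and every pair differed by far more than counting noise (chi-square per degree of freedom from 39.5 to 179). Where strand was not used in counting, reads of a gene and of an antisense partner cannot be told apart, so genes with exons overlapping another gene are uncertain. Small-input libraries are amplified, and reads without molecular identifiers are not independent molecules.

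The groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust, TMM normalization, filterByExpr, which left 15643 genes), with group as the only term and a Benjamini-Hochberg adjusted p threshold of 0.05. This unpaired fit is the primary test, fixed before the data were examined. CPM values are counts per 1e+06 of TMM-scaled library size, given as mean ± SD. Gene lists were tested with camera of limma 3.58.1 (log2 CPM, prior count 2, preset inter-gene correlation 0.01, 2-sided, adjusted over 28 lists). Of 365 list genes, 364 were found and 305 tested. The list of plasma cell genes had no tested member, and a sex-linked list served only to check the libraries.

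The same replicate numbers occur in both groups. A fit with the number as a block was planned as an alternative. Deviations from the group means correlated between same-numbered libraries at 0.02 to 0.25 over all 15643 tested genes. The lowest value, for number 3, was under the 0.1 set as the minimum for pairing, and 7 of 8 libraries correlated best with their own number. Over 6249 genes with a mean CPM of at least 20 the values were 0.28 to 0.61, and 8 of 8 libraries correlated best with their own number, but this check was chosen after seeing the data. The correlations over all genes therefore do not establish pairing. Same-numbered libraries did share differences, since 669 of 15643 genes passed an edgeR test of the number with the group as a term. The labels do not say what such libraries share. The deposited comparison does use the number: the authors' dispersions differed by at most 8.7e-04% from those of a DESeq2 model with number and group, over 29254 genes, and not from those of a model with group alone by so little (up to 7498%). On that ground the blocked fit is given beside the unpaired one. The numbers of calls of both fits had been seen when this was decided.

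On simulated data with the real means and library sizes (15643 genes, 100 changed per fold size), the unpaired fit on unpaired data recovered 9% of 2-fold and 59% of 4-fold changes, with 6.85% of calls false. With simulated pairing, the blocked fit recovered 37% and 75%, with 8.94% of calls false, and the unpaired fit 4% and 47%, with 1.92% false. The blocked fit on data without pairing had 13.1% false calls. The false shares thus lay above the nominal level for the blocked fit in both simulations and for the unpaired fit on unpaired data. Each comes from a single simulated data set. The false calls were 11 of 123 and 11 of 84 with the block, and 5 of 73 for the unpaired fit on unpaired data.

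Genes were named by a rule fixed before the data were examined. The rule takes the sort marker, the floxed gene and the markers excluded by the sort. It adds the 10 largest changes each way among genes past the threshold with a mean CPM of at least 20, no overlap of the 4 CPM values of the groups and no predicted or clone symbol. It also takes up to 4 called members per list by size of change, or the most abundant members, up to 2, where fewer than 2 passed. Applying the rule to the blocked fit was added later, and genes outside it are said to be chosen after their values were seen. Alternatives were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0, limma-voom, a test against a 1.5-fold change, leaving out each library, an estimated inter-gene correlation and fry. Settings of the blocked fit other than the block itself were added after seeing the data. Positions are 1-based, from GENCODE M21. Nothing mapped to a group was left out. Called members of the complement list are not reported here.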

Results

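The data comprised 8 RNA-seq libraries from YFP+ CD45-CD31- stromal cells of the mouse small intestine, 4 sorted as PDGFRα- and 4 as PDGFRα+. PDGFRα is a platelet-derived growth factor receptor on the surface of many intestinal fibroblasts. Total counts, in units of 1e+06, were 26.9, 20.9, 12.9 and 19.8 in PDGFRα- libraries 1 to 4 and 35.1, 23.1, 29.8 and 13.0 in PDGFRα+ libraries 1 to 4. The comparison asks how the transcriptomes of the sorted fractions differ. Values are CPM as mean ± SD (n = 4 libraries per group) unless stated otherwise.

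RNA of the sort marker itself did not differ detectably between the fractions. Pdgfra (ENSMUSG00000029231, chromosome 5, 75152292 to 75198215, GRCm38) stood at 652 ± 124 CPM in the libraries labelled PDGFRα- and 597 ± 69.2 CPM in those labelled PDGFRα+. The log2 fold change was -0.13 ± 0.17 (SE, edgeR adjusted p = 0.971), with a 95% interval from -0.50 to 0.24, and Pdgfra was higher in the PDGFRα+ library of 1 of 4 same-numbered pairs. The sort was on surface protein, which these data do not measure, so the RNA gives no check of the labels, and group names here mean the labels. Exons of Pdgfra overlap Gm42802 and Gm42803. Ltbr, the floxed lymphotoxin β receptor gene (ENSMUSG00000030339, chromosome 6, 125306571 to 125313885), stood at 67.9 ± 27.3 and 64.0 ± 9.21 CPM (log2 fold change -0.09 ± 0.25 SE, edgeR adjusted p = 0.991). Counts over the whole gene say nothing of single exons and do not check the deletion. The gates excluded cells with CD45 and CD31. Ptprc, which encodes CD45, was at 10.4 ± 11.4 and 1.67 ± 0.69 CPM and Pecam1, which encodes CD31, at 42.9 ± 59.5 and 22.7 ± 13.4 CPM, neither past the threshold (edgeR adjusted p = 0.469 and 0.970).

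Between the fractions, 30 genes were higher and 8 lower in PDGFRα+ cells. The largest named increase was in the proliferation marker Mki67 (chromosome 7, 135689784 to 135716361), from 3.63 ± 1.53 to 37.6 ± 8.52 CPM, 10.3-fold (log2 fold change 3.36 ± 0.34 SE, edgeR adjusted p = 0.00137). Among genes with a mean CPM of at least 20 it was followed by the cyclic nucleotide phosphodiesterase gene Pde1c at 4.74-fold, the LIM-domain gene Fhl2 at 4.17-fold, the septin gene Sept4 at 3.95-fold and the T-box transcription factor gene Tbx2 at 3.69-fold. Ptgs1, which encodes cyclooxygenase-1, rose 3.65-fold, the adhesion receptor gene Adgrl3 3.56-fold and the zinc finger gene Jazf1 3.54-fold. Hpse2, a heparanase family member (chromosome 19, 42786539 to 43388355), rose from 183 ± 40.4 to 594 ± 37.6 CPM (edgeR adjusted p = 0.00137), and the collagen VI chain gene Col6a5 from 209 ± 50.9 to 667 ± 181 CPM (edgeR adjusted p = 0.0088).

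The 8 genes lower in PDGFRα+ cells were all named by the rule. The BMP antagonist gene Chrdl1 (chromosome X, 143285674 to 143394262) was 3.20-fold lower, at 44.7 ± 7.88 and 14.0 ± 6.83 CPM (log2 fold change -1.68 ± 0.30 SE, edgeR adjusted p = 0.0399). The lipoprotein receptor gene Vldlr was 2.66-fold lower, Angpt1, a ligand of the endothelial receptor TIE2, 2.58-fold, the netrin gene Ntn4 2.47-fold and the proteoglycan gene Ogn 2.39-fold. Angptl1 was 2.23-fold lower, the serine protease gene Prss23 2.10-fold and the sterol hydroxylase gene Cyp27a1 1.97-fold, with edgeR adjusted p values of these 8 genes from 0.0111 to 0.0462. Exons of Ptgs1, Adgrl3, Angpt1, Angptl1 and Prss23 overlap antisense genes, and those of Sept4 overlap Gm11492 on the same strand. The count of 38 depended on single libraries. It was 11 without PDGFRα- library 2, 7 without PDGFRα- library 3, and 20, 15 and 10 without PDGFRα+ libraries 1, 2 and 3.

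With the replicate number as a block, 209 genes were higher and 146 lower (355 in all, edgeR), and the 38 genes above were among them. The correlation check over all genes did not establish that the numbers pair the libraries. Same-numbered libraries did share differences, with 669 of 15643 genes past an edgeR test of the number. In a single simulated data set of each kind, the blocked fit made 8.94% false calls on paired and 13.1% on unpaired data. The unpaired fit made 1.92% and 6.85%, and on paired data it recovered 4% of 2-fold changes against 37% with the block. The authors' deposited table, whose model includes the number, lists 386 genes higher and 423 lower. All 355 blocked calls are among these with the same sign. The rule applied to the blocked fit added the laminin chain gene Lama1 at 4.43-fold and the collagen VI chain gene Col6a4 at 4.10-fold as higher. It added as lower the sulfonylurea receptor subunit gene Abcc9 (log2 fold change -1.40), the retinoic acid receptor gene Rarg (-1.36), Mindy4 (-1.27) and the BMP family ligand gene Gdf6 (-1.27). None of these 6 passed the unpaired test, with edgeR adjusted p values of 0.0612 for Mindy4 to 0.430 for Gdf6. Exons of Col6a4 and Abcc9, and further below those of Bmp5, Cd81, Rspo3, Fn1, Nid2, Col15a1, Col4a1, Vcam1, Bmp6, Foxf2, Fgf10, Ereg, Lox, Dusp1 and Jun, overlap genes on the other strand, and those of Col3a1, Hgf and Top2a overlap genes on the same strand. The blocked count was 187 without number 1 and 97 without number 3.

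**Figure D1:**
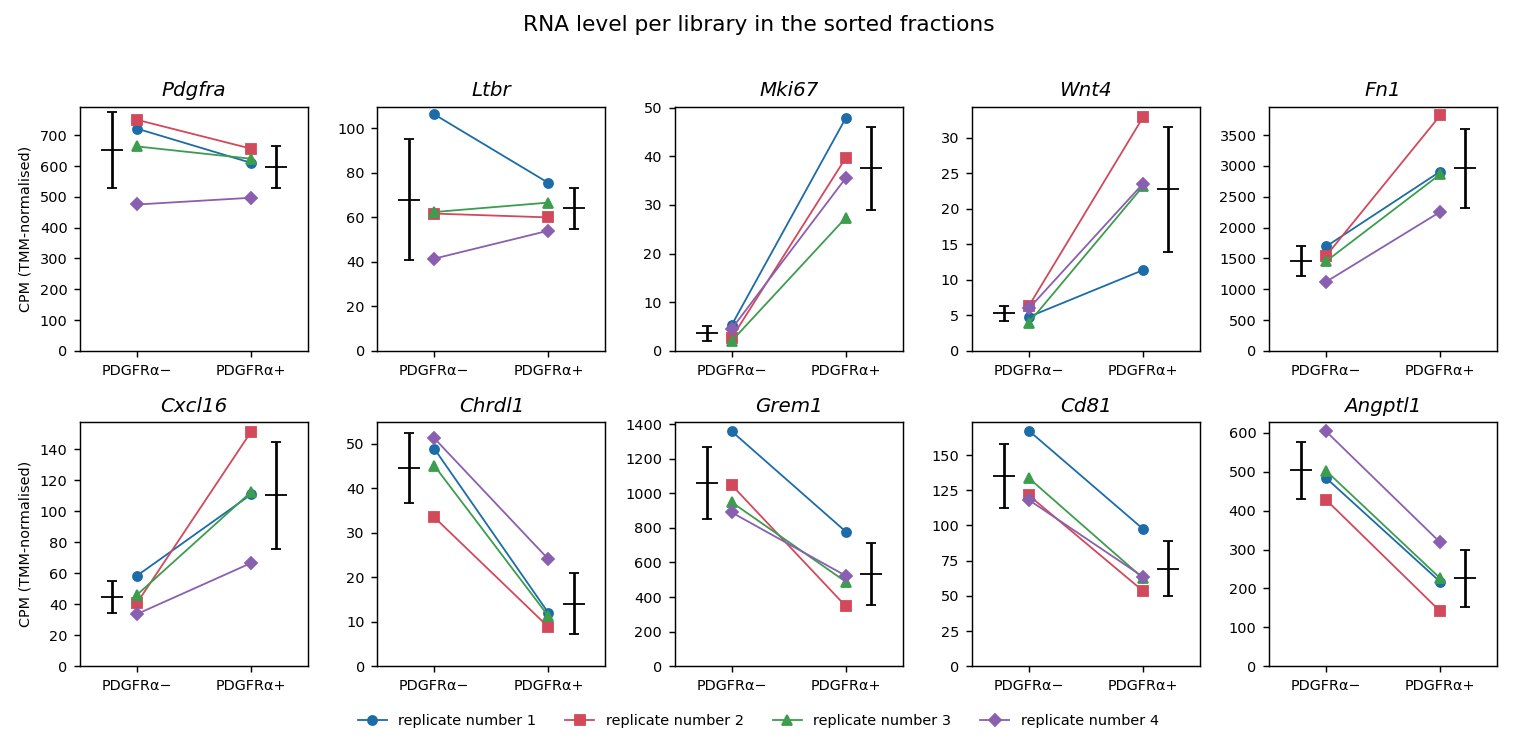
CPM of 10 named genes in each library (y axes from 0), with lines joining libraries of the same replicate number and, beside them, the mean with SD of 4 libraries. Pdgfra and Ltbr overlap between the fractions, Mki67, Wnt4, Fn1 and Cxcl16 are higher and Chrdl1, Grem1, Cd81 and Angptl1 lower in all 4 PDGFRα+ libraries. Grem1 and Cd81 passed the threshold only in the blocked fit.

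In the unpaired fit 5 list members passed the threshold, Wnt4, Fn1, Cxcl16 and Mki67 as higher and Chrdl1 as lower. For each list below, the counts come from the blocked fit, over all genes tested, unless the unpaired fit is named. Camera called 9 of 28 lists without the block and 11 with it, and called none in either fit when the inter-gene correlation was estimated from the data (lowest adjusted p = 0.135 and 0.459). That setting was stricter also for a list with an estimated correlation under the preset value (hedgehog response with the block, 0.0018). Losing a call there does not by itself show that genes of a list move together.

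Of 10 tested genes associated with intestinal telocytes, the subepithelial fibroblasts with high PDGFRα, 1 was called higher in PDGFRα+ cells without and 3 with the block, and 9 and 8 had positive log2 fold changes. The untested list genes were Foxl1 and Vstm2a. Foxl1 had 0 counts in every library. So had Foxf1, Igf2, Tubb3, Igkc, Higd1b, mt-Nd4l, mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8 of other lists, while mt-Co1 had at least 12314 in each. A count of 0 for such a gene is therefore not read as absence of its RNA, and the cause was not tested. Vstm2a had 0, 0, 58 and 46 counts in PDGFRα- libraries 1 to 4 and 0, 0, 3 and 2 in PDGFRα+ libraries 1 to 4. Wnt4 (chromosome 4, 137277489 to 137299726), which encodes a WNT ligand, stood at 5.27 ± 1.08 and 22.7 ± 8.81 CPM (log2 fold change 2.10 ± 0.35 SE, edgeR adjusted p = 0.0265 unpaired). The BMP ligand gene Bmp5 (20.4 ± 8.82 and 59.1 ± 26.7 CPM) and the WNT antagonist gene Frzb (3.37 ± 4.13 and 18.9 ± 12.8 CPM) passed the blocked test alone (edgeR adjusted p = 0.00215 and 0.00192). Adjusted over the list alone 3 were higher in both fits, and camera gave an adjusted p of 0.00616 without and 0.0122 with the block (adjusted p = 0.395 and 0.459 with an estimated correlation). Genes of trophocytes and adventitial fibroblasts shifted as a list to lower values (camera adjusted p = 0.00682 and 0.0104, and 0.395 and 0.459 with an estimated correlation). Grem1, a BMP antagonist gene (chromosome 2, 113746164 to 113758646), stood at 1061 ± 209 and 534 ± 180 CPM, Cd81, a tetraspanin gene, at 135 ± 22.5 and 69.3 ± 19.4 CPM, and Rspo3, which encodes a WNT-enhancing R-spondin, at 126 ± 25.5 and 75.7 ± 22.8 CPM. These 3 were called lower with the block (edgeR adjusted p = 5.6e-04, 6.5e-04 and 0.0348) and not without it (0.113, 0.0723 and 0.315). Igfbp5, an IGF-binding protein gene, went the other way (log2 fold change 1.49 ± 0.15 SE with the block). With the p-values adjusted over the list alone, 1 of 13 was higher and 6 lower with the block, and 3 lower without it.

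Of 15 basement membrane genes, 10 had positive log2 fold changes in both fits, and 6 were called higher with the block and 0 without it (edgeR, 8 without the block at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom). Col18a1 stood at 348 ± 139 and 741 ± 340 CPM, Nid2 at 60.3 ± 27.5 and 131 ± 18.5 CPM, Col15a1 at 762 ± 117 and 1333 ± 392 CPM and Lama4 at 351 ± 74.4 and 564 ± 127 CPM, with blocked edgeR adjusted p values of 1.4e-04, 0.00613, 0.00103 and 0.0144. Col4a1 and, named after its values were seen, Lamb1 were also called (log2 fold changes 0.47 and 0.63). There were 8 higher and 1 lower with the block, and 7 higher without it, adjusted over the list alone. The camera adjusted p was 0.00531 and 0.00982 (0.395 and 0.459 with an estimated correlation). Without number 3 the count fell to 2 and without number 1 to 4. The interstitial matrix list moved both ways, with 2 of 16 members higher and 3 lower (2 and 7 adjusted over the list alone with the block, 1 and 3 without it) and camera adjusted p = 0.385 and 0.373. Fn1, the fibronectin gene (chromosome 1, 71585520 to 71653200), rose from 1452 ± 242 to 2961 ± 644 CPM (edgeR adjusted p = 0.0461 unpaired), and Fbln2 was called with the block at a log2 fold change of 0.58. The higher members were 1 without number 2, 3 or 4. The fibrillar collagen genes Col1a1, Col1a2 and Col3a1, the most abundant of the list, were lower with the block (log2 fold changes -0.54, -0.55 and -0.50, edgeR adjusted p = 0.0155, 0.0137 and 0.0107) and not past the threshold without it (0.378, 0.297 and 0.297), nor without number 1 or number 3, where 0 interstitial matrix genes were called lower. These 3 genes took 11.3% to 14.4% of all counts in PDGFRα- and 8.63% to 10.5% in PDGFRα+ libraries. Of the matrix remodelling list 1 of 15 members was called, the lysyl oxidase gene Lox as lower (log2 fold change -0.60), with 0 lower without number 1 or number 3, and 1 higher and 2 lower without number 2, with 2 higher and 3 lower adjusted over the list alone and camera adjusted p = 0.975 and 0.783.

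Ligands and modulators of BMP and WNT signalling had calls in both directions with the block. In the BMP list 2 of 16 members were higher, Bmp5 and Bmp6, and 3 lower, Chrdl1, Grem1 and, named after its values were seen, Id2. Without number 3 the counts were 0 and 2. The counts adjusted over the list alone were 4 and 5, and 2 and 4 without the block. For the whole list camera gave adjusted p = 0.638 and 0.609, and in the blocked fit the list's median log2 fold change was 0.11 while its mean was -0.07 and the test pointed down. In the WNT list 2 of 16 were higher, Wnt4 and Frzb, and 3 lower, Wnt9a (log2 fold change -0.86), Rspo3 and, named after its values were seen, the WNT antagonist gene Dkk2 (-0.62). Without number 1 or number 4 the lower members were 1, and without number 3 they were 0. Adjusted over the list alone the counts were 2 and 5 with the block and 2 and 3 without it, and camera gave adjusted p = 0.0685 and 0.0895. Of the hedgehog response list 2 of 8 members were higher, the receptor and target gene Ptch1 and the forkhead gene Foxf2 (log2 fold changes 0.65 and 1.12, edgeR adjusted p = 0.0189 and 0.0170), and 4 adjusted over the list alone (3 without the block). Camera gave adjusted p = 0.0215 and 0.00982 (0.395 and 0.459 with an estimated correlation), and 0 members were called without number 3. The retinaldehyde dehydrogenase genes Aldh1a3 and Aldh1a2, which act in retinoic acid synthesis, were the called members of 10 in the retinoid list, at 2.44-fold and 1.72-fold higher, with 1 called without number 3. Adjusted over the list alone 3 were higher and 2 lower (3 and 0 without the block), with camera adjusted p = 0.405 and 0.430.

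Of 19 chemokine and cytokine genes, 5 were higher and 1 lower. Cxcl16 (chromosome 11, 70453983 to 70459984), a transmembrane chemokine gene whose exons overlap Zmynd15 on the other strand, rose from 44.8 ± 10.4 to 110 ± 34.6 CPM (edgeR adjusted p = 0.0462 unpaired). Cxcl5 and Cxcl9 were called with the block (log2 fold changes 1.84 and 1.09), as were Ccl11 and Il33, named after their values were seen (0.85 and 0.84), and Ccl7 was lower (-0.87). Without number 1 the counts were 3 and 0, without number 2 they were 5 and 0 and without number 3 they were 4 and 0. In all 6 were higher and 2 lower adjusted over the list alone (4 and 0 without the block), with camera adjusted p = 0.0215 and 0.0412 (0.395 and 0.459 with an estimated correlation). Of 16 growth factor ligand genes 5 were higher with the block, the epithelial mitogen genes Fgf10 (log2 fold change 2.30), Ereg (0.89) and Hgf (0.74), the neurotrophic factor gene Gdnf (1.53) and Igf1 (0.65). The count of 5 was 2 without number 1 or number 2 and 1 without number 3. Adjusted over the list alone 6 were higher and 3 lower (5 and 1 without the block). Camera gave adjusted p = 0.346 and 0.373, with a median log2 fold change of -0.07, a mean of 0.11 and an upward test in the blocked fit. Of 9 tested lymphoid stroma genes, 3 were higher and also 3 when adjusted over the list alone (both fits), the B cell survival factor gene Tnfsf13b, the adhesion molecule gene Vcam1 and Pdpn (log2 fold changes 1.19, 0.73 and 0.49), with camera adjusted p = 0.223 in both fits. The count was 1 without number 1 and 0 without number 2 or number 3. None of 15 genes of lymphotoxin β receptor and NF-κB signalling was called in either fit or adjusted over the list alone. At an unadjusted p under 0.05 there were 0 of them without and 1 with the block (edgeR), and DESeq2 and limma-voom called 0 in both fits. Camera gave adjusted p = 0.975 in both.

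Contractile genes did not shift as a list. Of 14 smooth muscle genes 1 was called, Myocd, which encodes a coactivator of smooth muscle transcription (31.1 ± 17.2 and 70.8 ± 38.8 CPM, blocked log2 fold change 1.22 ± 0.16 SE), and 1 was higher and 1 lower adjusted over the list alone (camera adjusted p = 0.837 and 0.756). Myh11, the smooth muscle myosin gene, stood at 550 ± 315 and 448 ± 181 CPM. Of 10 pericyte genes Cspg4 was higher (log2 fold change 1.17) and Abcc9 lower, the first not without number 1 and neither without number 3, with 1 and 2 adjusted over the list alone (1 and 1 without the block) and camera adjusted p = 0.364 and 0.153. Rgs5, the most abundant pericyte gene, stood at 955 ± 345 and 820 ± 246 CPM. The complement list, with 10 tested genes, had camera adjusted p = 0.778 and 0.203. No interferon response gene of 14 was called in either fit (edgeR, 0 also at an unadjusted p under 0.05 and by DESeq2 and limma-voom), with camera adjusted p = 0.947 and 0.783.

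Of 13 tested cell cycle genes, 11 had positive log2 fold changes in both fits, and 1 was called higher without and 3 with the block. Mki67 passed both tests, and Top2a (3.83 ± 1.57 and 26.3 ± 18.4 CPM) and Cenpf (1.76 ± 1.28 and 14.5 ± 6.38 CPM), genes of a topoisomerase and a centromere protein, passed the blocked test (edgeR adjusted p = 0.0184 and 0.0157). The count was 8 adjusted over the list alone (6 without the block). Camera gave adjusted p = 5.4e-09 without and 3.4e-07 with the block (0.135 and 0.459 with an estimated correlation). Without number 3 the called members fell to 1. Of 15 genes that respond to tissue dissociation, all had negative log2 fold changes, and 0 were called without the block (edgeR, 6 at an unadjusted p under 0.05, 0 by DESeq2 and limma-voom). With the block 5 were called lower, Fos, Dusp1, Socs3, Jun and, named after its values were seen, Junb (log2 fold changes -0.73, -0.68, -0.62, -0.62 and -0.53), and all 15 adjusted over the list alone (3 without the block). Camera gave adjusted p = 4.0e-06 and 3.4e-07 (0.395 and 0.459 with an estimated correlation). The count was 1 without number 1 and 0 without number 3. Mitochondrially encoded genes had 0 of 7 members called (edgeR, 0 without and 5 with the block at an unadjusted p under 0.05, 0 by DESeq2 and limma-voom), with camera adjusted p = 0.0256 and 0.0378 (0.548 and 0.556 with an estimated correlation) and a median log2 fold change of -0.26 in both fits.

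Markers of other cell types were lower in PDGFRα+ libraries as lists where camera called them, and no single marker was called by edgeR in either fit. Leukocyte markers had camera adjusted p = 0.0215 without and 0.0591 with the block (0.548 and 0.556 with an estimated correlation), and their summed level was 99.0 ± 54.0 and 48.2 ± 20.6 CPM. The unpaired call was lost without PDGFRα- library 3 or 4 or PDGFRα+ library 2 or 3 (0.203, 0.151, 0.0566 and 0.0697). Blood endothelial markers had 0.223 and 0.0378 (0.786 and 0.557 with an estimated correlation) and summed to 290 ± 347 and 134 ± 58.8 CPM, with 809 CPM in PDGFRα- library 4 and 96.4, 108 and 147 CPM in the other PDGFRα- libraries. Without library 4 the unpaired list test pointed up (adjusted p = 0.558). Lymphatic endothelial markers had 0.182 and 0.00971 (0.635 and 0.459 with an estimated correlation) and summed to 100.5 ± 97.9 and 36.1 ± 26.5 CPM. Markers of interstitial cells of Cajal had 0.425 and 0.0424 (0.612 and 0.475 with an estimated correlation). Their summed level hardly differed, at 27.9 ± 10.1 and 27.4 ± 11.1 CPM, and was higher in the PDGFRα+ library of 3 pairs. Etv1, the most abundant of them, went up in the authors' comparison but missed the threshold (log2 fold change 1.16, DESeq2 adjusted p = 0.0970). Ano1 of the same list was lower there (-1.48, DESeq2 adjusted p = 0.0380). Epithelial markers had 0.0732 and 0.0505, with sums of 209 ± 288 and 12.2 ± 14.2 CPM, of which PDGFRα- library 2 held 631 and there the lysozyme gene Lyz1, removed by the filter on low counts, 571. The epithelial list was called lower without that filter (7.8e-05), without PDGFRα- library 1 (0.0494) and without PDGFRα+ library 4 (0.0193). Enteric glia had 0.629 and 0.714, enteric neurons 0.790 and 0.975 and mesothelium 0.382 and 0.177. Plasma cell genes, not tested, summed to 0.886 ± 1.27 and 10.8 ± 18.0 CPM, higher in the PDGFRα+ library of 3 pairs, with 37.7 CPM in PDGFRα+ library 2. At an unadjusted p under 0.05 with the block edgeR had 3 of 9 blood endothelial, 4 of 5 lymphatic, 3 of 4 Cajal cell, 2 of 8 glial and 2 of 7 epithelial markers and 0 of 11 leukocyte markers, and DESeq2 with the block called 3, 3, 2, 1, 2 and 0 of them and limma-voom with the block 2, 2, 1, 0, 0 and 0. Without the block edgeR had 1, 0, 1, 0, 0 and 2 at an unadjusted p under 0.05, DESeq2 called 1 epithelial marker and limma-voom 0 of any. For neurons and mesothelium all these counts were 0.

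**Figure D2:**
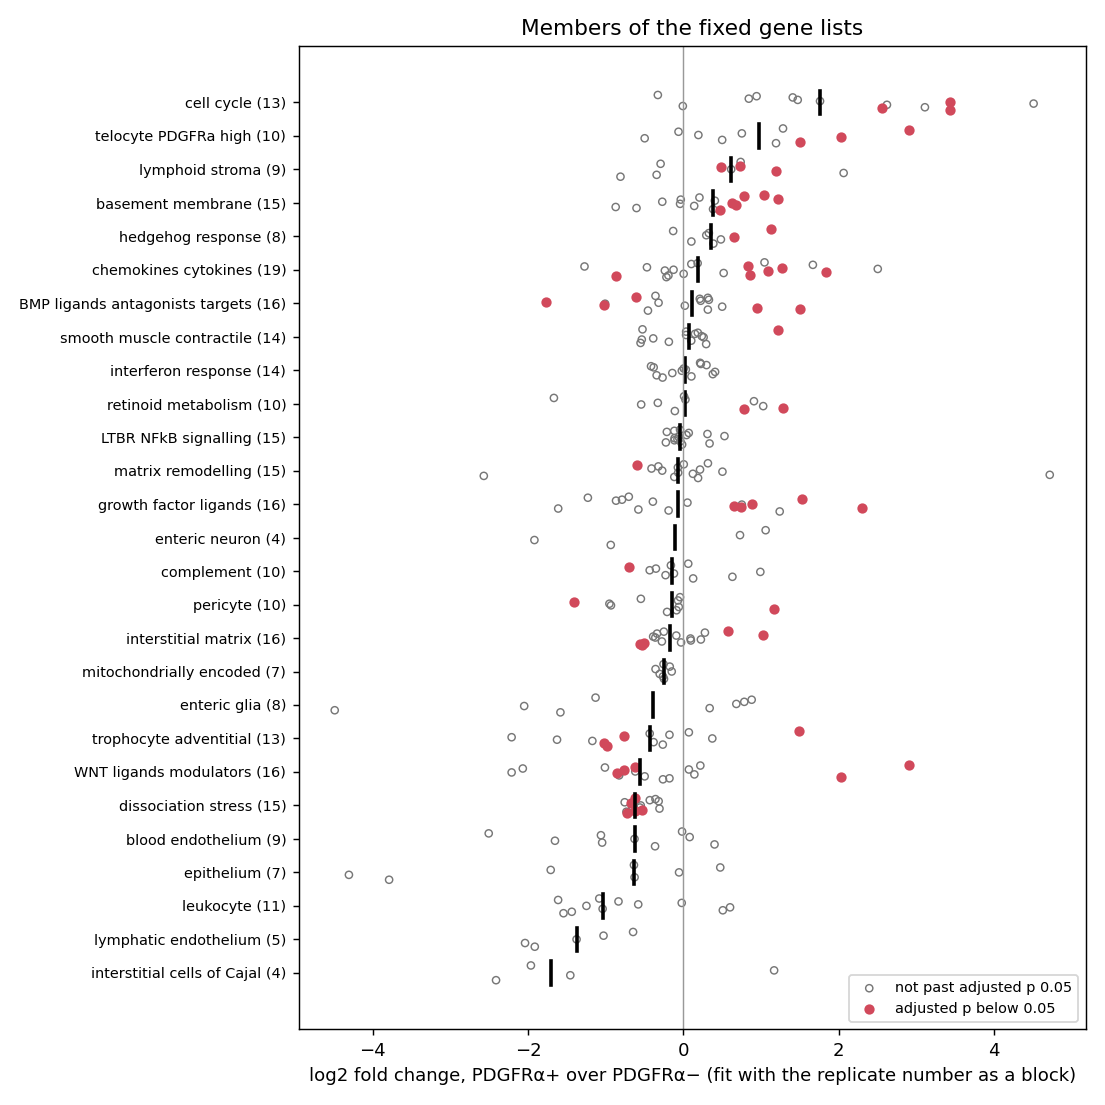
Log2 fold changes (PDGFRα+ over PDGFRα-, blocked edgeR fit) of the tested members of each list with at least 4 tested members, 1 point per gene, with the number tested in parentheses. Filled points have an adjusted p under 0.05 and black bars are list medians. The cell cycle list has the highest median (1.76) and interstitial cells of Cajal the lowest (-1.71).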

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

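Libraries far from the other 3 of their group were sought in 210 groups of 4 values, and 13 stood apart, where chance gives about 10.5. Of the tests below, those of the spread of Pdgfra, of the gates holding the same cells, of other cell types, of sex and of leukocytes by fraction were chosen after the result was seen.

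Pecam1 stood at 132 CPM in PDGFRα- library 4 against 11.7 to 15.4 in the other PDGFRα- libraries, and the endothelial gene Plvap at 166 against 3.42 to 19.0. Sept4 was at 45.3 CPM in PDGFRα- library 1 (others 17.8 to 21.5), Frzb at 9.53 there (others 0.65 to 1.76) and H2-K1 at 1521 there (others 317 to 516). Col6a4 was at 16.5 CPM in PDGFRα- library 3 (others 51.6 to 55.0), and Fgf10 at 5.22 there (others 2.16 to 2.66). Zbtb16 was at 770 CPM in PDGFRα- library 2 (others 141 to 238). In PDGFRα+ library 2, Ptgs1 was at 84.4 CPM (others 39.3 to 41.6), Fgf10 at 26.1 (others 11.1 to 12.6) and Cenpf at 24.1 (others at least 10.9). Mindy4 was at 32.1 CPM in PDGFRα+ library 3 (others 19.0 to 19.3) and Ddx3y at 175 in PDGFRα+ library 4 (others 99.4 to 108).

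The count of 38 genes was matched by 1 of 35 splits of the 8 libraries, the real one, and the highest other split gave 1. Chance is excluded at the 0.05 level only if the libraries are unpaired, which is doubtful, since 669 of 15643 genes passed an edgeR test of the number. If the numbers pair the libraries, 8 splits part all 4 pairs, too few for a share under 0.05. The same holds for the blocked count of 355, where the highest other split gave 0. For the 9 lists called by camera, 2 of 35 splits gave as many, the highest other split also 9, so chance is not excluded for the number of lists.

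The first pattern is that Pdgfra RNA was alike in fractions sorted on its protein. Labels swapped within some pairs are argued against, since 151 of 6249 genes moved by over 0.5 (log2) the same way in all 4 pairs as labelled, and at most 8 under the 7 patterns with pairs swapped. A 2-fold higher level hidden by spread is argued against by the upper 95% limit of 0.11 for the blocked log2 fold change. Gates holding the same cells are argued against by the splits, with 38 unpaired calls against at most 1 in the others, only if the libraries are unpaired. If they are paired, the splits are too few for a share under 0.05. The blocked edgeR test itself then argues against the same cells in both gates. It called 355 genes as labelled and at most 0 in the other splits that part all pairs. On simulated paired data it made 8.94% false calls. A swap of all 4 pairs stays open. Of 10 tested telocyte genes, of cells with high PDGFRα, 9 without and 8 with the block had positive log2 fold changes. Of 13 trophocyte and adventitial genes 3 had positive ones in both fits. Most members of both lists thus ran the way the labels do. Igfbp5 of the second list and the untested telocyte gene Vstm2a went against the labels. A difference between RNA and surface protein stays open and untested.

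The second pattern is the higher median level of cell cycle genes in PDGFRα+ libraries, found in the same data. Unequal depth is argued against, since Mki67 kept a blocked log2 fold change of 3.51 after all libraries were thinned to the smallest total. Cells of other types in the PDGFRα+ gate, though the sort excluded CD45 and CD31, are argued against only in part. The medians of 40 markers of such cells were 0.0249, -0.25, -1.10 and -1.12 (log2, PDGFRα+ over PDGFRα-) in pairs 1 to 4. They were neither below 0 in all pairs nor above 0 in most, so they do not decide for all pairs. Those of 13 cell cycle genes were 2.01, 2.02, 1.00 and 0.81. In pairs 3 and 4 the markers thus fell while the cell cycle genes rose. This argues against cells like those in PDGFRα- libraries as the main source in these 2 pairs. Summed blood endothelial markers in pair 3 and glial markers in pair 4 did rise. Pairs 1 and 2 and dividing cells of another kind stay open. Plasma cell genes, not among the 40, summed to 0.886 ± 1.27 CPM in PDGFRα- and 10.8 ± 18.0 CPM in PDGFRα+ libraries, with 37.7 CPM in PDGFRα+ library 2 and 0 in PDGFRα+ library 4, where Mki67 was at 35.5 CPM against 4.52 in PDGFRα- library 4. More dividing cells among the PDGFRα+ stromal cells is a biological hypothesis that was not tested.

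The third pattern, genes of complement and MHC class I that differed between replicate numbers within both fractions, was picked after the values were seen. C3 averaged 15792 CPM in number 1 and 1178 in number 4, C4b 2146 and 188 and H2-D1 2110 and 465. Sex of the mice is argued against, since the lowest count of the Y-linked gene Ddx3y in any library was 1319. Leukocytes are argued against in PDGFRα- libraries 1 and 4. There the median log2 ratio of number 1 to number 4 over 11 leukocyte markers was -0.84 (SE 0.42), at most -0.0147 with 2 SE added. That of 11 complement and MHC class I genes was 2.26 (SE 0.35). Each SE here is over genes, for 1 library against 1 other, and does not measure the spread between libraries. In PDGFRα+ libraries the ratios do not decide about leukocytes. The marker median of 0.60 (SE 0.59) reaches 1.78 with 2 SE added. The 11 genes' median of 2.09 (SE 0.33) falls to 1.44 with 2 SE taken off. The sort excluded CD45, and in PDGFRα+ library 1 the leukocyte markers summed to 78.9 CPM beside 12186 CPM of C3 and 1943 CPM of H2-D1. In PDGFRα- libraries 3 and 4 these markers summed to more, 147 and 144 CPM. Yet each of the 11 genes was lower there, with C3 at 4997 and 1201 CPM. This comparison, also chosen after the values were seen, argues against leukocytes like those as the main source in PDGFRα+ library 1. Leukocytes of another kind stay open. The marker medians had opposite signs in the fractions, so an earlier test of their sign decided nothing. A difference between mice or days stays open and untested, since the labels give neither.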

How the results depend on the processing

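Settings of the blocked fit, and DESeq2 and limma-voom with the block, were chosen after seeing the data. The unpaired count of 38 (30 higher, 8 lower) was 35 with DESeq2 size factors and 30 with limma-voom. It was 277 (167 and 110) without the filter on low counts, 272 (156 and 116) with DESeq2, 6 (6 and 0) against a 1.5-fold change, 355 (209 and 146) with the replicate block, 809 (386 and 423) with DESeq2 and the block and 582 (301 and 281) with limma-voom and the block. Leaving out 1 library gave 7 to 48 genes (7 to 37 higher, 0 to 11 lower). Fewer libraries enter these fits, and otherwise the cause was not tested. At an unadjusted p under 0.05 there were 1087 genes, where chance gives 782. The blocked count of 355 was 348 with DESeq2 size factors (192 higher, 156 lower), 395 after thinning all libraries to the smallest total, 681 (358 and 323) without the filter, 54 (49 and 5) against a 1.5-fold change and 38 (30 and 8) with no replicate block. Leaving out a number gave 97 to 298 (76 to 184 higher, 21 to 114 lower). DESeq2 size factors moved the median log2 fold change by -0.01.

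Of 25 named genes called in the unpaired fit, all 25 kept call and direction with the block, DESeq2 or no filter, 24 with DESeq2 size factors, 21 with limma-voom, and 6 to 24 when 1 library was left out, with 0 reversals. Of 80 named genes called with the block, 79 kept it with DESeq2 size factors and after thinning, 80 with no filter, DESeq2 or limma-voom, and 55, 66, 40 and 73 without numbers 1 to 4, with 0 reversals. Genes that were not called reversed sign when a library was left out, with log2 fold changes of Ltbr from -0.26 to 0.21, Pecam1 from -1.23 to 0.79, Myh11 from -0.60 to 0.0891, Rgs5 from -0.40 to 0.0627 and C3 from -1.40 to 0.36. With the block and a number left out, Ltbr ran from -0.15 to 0.14 and Pecam1 from -0.93 to 0.25.

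The 9 lists called by camera became 11 with the block and 5 to 12 with a library left out (5 without PDGFRα+ library 3). They became 2 with fry (cell cycle and basement membrane). With fry and the block there was 1 (lymphoid stroma, adjusted p = 0.0322, where cell cycle and basement membrane missed at 0.0562). With an estimated correlation there were 0, without or with the block. Genes that move together do not account for every such loss. The hedgehog list in the blocked fit had an estimated correlation of 0.0018, under the preset 0.01. Its unadjusted camera p still went from 0.00175 to 0.0487 in that setting. The hedgehog response call was lost without PDGFRα- library 1 or 4 or PDGFRα+ library 2, 3 or 4 (highest adjusted p 0.0881), the chemokine call without PDGFRα- library 2 or PDGFRα+ library 1 or 3 (highest 0.0981), and the mitochondrially encoded call without the filter (0.0911) or without any library but PDGFRα- library 1 and PDGFRα+ library 2 (highest 0.203). Lists not called gained a call without PDGFRα- library 2 (lymphatic endothelium, 0.0184), PDGFRα+ library 1 (WNT, 0.0480) or PDGFRα+ library 4 (lymphatic endothelium, mesothelium and WNT, 0.0474 each), all lower. Lists that reversed direction were not called with all 8 libraries and no block, and their adjusted p is given a minus sign for a lower list. Of these, interferon response was called higher without PDGFRα+ library 4 (0.0244), and blood endothelium lower without PDGFRα- library 2 (-0.0411) and with the block (-0.0378). With a library left out, smooth muscle ran from -0.986 to 0.801, receptor and NF-κB signalling from -0.857 to 0.974, enteric glia from -0.857 to 0.982, enteric neurons from -0.789 to 0.925, blood endothelium from -0.657 to 0.558, complement from -0.748 to 0.575, matrix remodelling from -0.982 to 0.986 and interferon response from -0.812 to 0.923. The ends of these ranges are the largest adjusted p each way, so they are the weakest results and not extremes of effect. For smooth muscle the strongest was -0.0844, without PDGFRα- library 1. Receptor and NF-κB signalling was at -0.996 with DESeq2 size factors, -0.975 with the block and -0.987 with the block and an estimated correlation. Without the filter enteric neurons were at -0.565 and matrix remodelling at 0.736, and fry put matrix remodelling at 0.994. The cause was not tested. In the unpaired fit the median and the test differed in sign for receptor and NF-κB signalling, enteric glia, enteric neurons, mesothelium and growth factor ligands.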

Other observations

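The genes in these paragraphs were chosen after their values were seen. The genes Vcan, Tnc and Hmcn1 were higher in PDGFRα+ cells in both fits. The proteoglycan gene Vcan stood at 205 ± 37.9 and 618 ± 94.6 CPM, the tenascin gene Tnc at 340 ± 123 and 974 ± 164 CPM and the hemicentin gene Hmcn1 at 245 ± 28.3 and 667 ± 116 CPM (n = 4 per group, edgeR adjusted p = 0.00189, 0.0165 and 0.00253 unpaired). Adamdec1, which encodes a metalloprotease, rose from 1611 ± 254 to 4810 ± 1647 CPM (edgeR adjusted p = 0.0149). Apoe, an apolipoprotein gene, and Hpgd, a prostaglandin-degrading enzyme gene, were lower with the block (log2 fold changes -0.98 and -0.94) and missed the unpaired threshold (edgeR adjusted p = 0.0612 each). Groups did not overlap for 790 of the tested genes, 5.05%, where chance gives 2.86%.

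Libraries also differed by replicate number within both fractions, and 669 of 15643 genes passed an edgeR test of the number with the group as a term. Among them were 11 of 14 interferon response genes, 10 of 14 smooth muscle genes, 7 of 10 complement genes and 7 of 15 dissociation genes, and 0 of 13 cell cycle genes. The glucocorticoid-induced genes Fkbp5, Zbtb16 and Tsc22d3 averaged 149.8, 663 and 193 CPM in number 2 and 24.8, 128 and 46.8 CPM in number 3. Acta2, the smooth muscle actin gene, averaged 106 CPM in number 1 and 456 CPM in number 2. Serpina3n, an acute phase gene, averaged 1101 CPM in number 1 and 87.7 CPM in number 4.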
